A study of Arabidopsis thaliana with 12 samples.

How the data were processed

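RNA was extracted from 10-day-old Arabidopsis seedlings grown in days of 16 h light and 8 h dark, and libraries were made with a TruSeq RNA kit from fragments of about 300 bp and sequenced as paired reads on an Illumina HiSeq instrument, per the labels' protocols. The 3 replicates of each group are biological replicates raised and processed separately from germination on, per the labels. Groups were taken from the sample titles and genotype and treatment labels, which give 4 groups of 3 libraries. The deposited tables hold 1 value per gene and library. They were read as TPM from the values themselves, because each library sums to nearly the same total (between 998197.5 and 998680.8) with values that are not whole, and the deposited TPM were used without change. The aligner, the counting tool, its strand setting and any filter are not given in the sources used here. The submitters' processing notes name TAIR10 as the genome build.

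TPM divides by transcript length and by the library's total, so it keeps no read depth, and no interval or detection limit based on counts can be given. A gene's TPM also depends on every other gene in the library, so a rise of abundant genes lowers the values of all others. A value of exactly 0 may be a failed estimate: 376 genes were at 0 in 1 library and above 5 TPM in another of the same group, 282 of them under 300 bp. Genes with such values are said to be listed at 0 and are given library by library. 7294 loci were at 0 in every library. No 2 libraries were identical among the 66 pairs.

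Genes were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment across genes at 0.05, in 1 fit of the 4 group means over all 12 libraries. Genes with at least 1 TPM in at least 3 libraries entered, 19922 in all. Fold changes on this scale understate the change of genes near or below 1 TPM. Means and SD are of TPM over 3 libraries, and ± after a log2 change is its SE. The comparisons were UV-B against white light in Col-0, uvr8 against Col-0 under UV-B, ABA against white light in Col-0, uvr8 under UV-B against Col-0 in white light, and UV-B against ABA in Col-0. The fit was tested on simulated data made from the real means and spread, with 200 of 19922 genes changed. It recovered 83% of the genes changed by 1 log2 unit and 99% of those changed by 2 in the UV-B comparison, 85% and 98% for uvr8, 88% and 98% for ABA, 83% and 98% for uvr8 against white light, and 90% and 100% for UV-B against ABA.

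The tests, their alternatives, the lists and the rule for named genes were fixed before the data were examined. The 21 gene lists held 362 members, of which 361 were used. BG1 was dropped because its locus carries another symbol and that name belongs to another locus in the annotation. The lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with the correlation estimated from the data. In the seed storage list none of 4 members passed the filter on low values, so it was not tested. Calls held with an estimated correlation for the photomorphogenesis, flavonoid and clock lists with UV-B and in uvr8, for the drought list with ABA, and for the photomorphogenesis and drought lists between UV-B and ABA. Named genes were UVR8, then for each of UV-B, uvr8 and ABA the 5 highest and 5 lowest changes with group ranges that do not overlap and at least 5 TPM in the higher group, the 3 largest changes in each of the 5 lists on UVR8 photomorphogenesis, flavonoids and ABA, and the largest in every other list. HY5, CHS, ELIP1 and other genes named by the rule in 1 comparison are also described in the others. Not every gene that the rule names is described.

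The alternatives were TMM-style scaling of the TPM (trimming 30% of log ratios and 5% of mean levels), no filter on low values, limma without the trend, a pseudocount of 0.1, only the 2 groups compared, the replicate number as a block, a minimum log2 change of 1, each library left out in turn, and fry for the lists. TPM rescaled without ribosomal RNA, organelle-encoded genes and genes under 300 bp, and TMM-style scaling of the lists, were chosen after seeing the data. Overlaps of calls were set beside independent lists and beside 20 simulations of unchanged groups that share libraries in the same way.

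Gene positions are those of the TAIR10.1 annotation, to which 32548 of the 32833 locus identifiers matched by name. The values are per gene and carry no position of their own, so no coordinate was converted. Exons of 346 list and named genes were aligned with BLAST+ 2.17.0 to those of all other genes. Of the 83 named genes, 3 have a copy of at least 95% identity over at least 150 bp (PRR9, PHT1;1 and LDOX), 13 share exon sequence with an overlapping gene, and 2 are under 300 bp. How reads were divided between copies or overlapping genes is not given in the sources used here, so these values are uncertain. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.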

Results

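Transcript levels were measured by RNA sequencing in 10-day-old seedlings of Arabidopsis thaliana, comparing Col-0, the common wild-type accession, with uvr8, a mutant of the gene for the UV-B photoreceptor UVR8. The 12 libraries formed 4 groups of 3 biological replicates. These were Col-0 in white light, Col-0 in white light plus UV-B at 5 µmol m-2 s-1, uvr8 under the same UV-B, and Col-0 in white light with 50 µM abscisic acid (ABA), a hormone of drought and seed dormancy. Each treatment lasted 3 h, and the first 3 of these groups received no ABA. No uvr8 library from white light was analysed here. The values are in TPM, transcript abundance scaled to a fixed total per library, for 32833 loci, a unit that keeps no trace of the number of reads, so the depth of each library is unknown. Between 18557 and 19214 genes per library reached 1 TPM. Spearman correlations across genes lay between 0.976 and 0.98 within groups and between 0.947 and 0.978 across groups. The smallest adjusted p-values below rest on 3 libraries per group and on a spread estimated from all 12.

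UVR8 itself (AT5G63860, chromosome 5, 25554416 to 25559499, minus strand) was examined first in every library. In Col-0 in white light it stood at 105.55, 107.19 and 107.46 TPM, and under UV-B at 66.88, 73.77 and 71.07 TPM. The 3 uvr8 libraries held 20.78, 23.61 and 21.09 TPM, below every Col-0 library. The ABA libraries held 95.2, 89.96 and 98.79 TPM. Under UV-B the UVR8 transcript differed between uvr8 and Col-0 by -1.65 ± 0.07 (SE) on the log2 scale (adjusted p = 5.22e-09). It fell by 0.59 ± 0.07 on the log2 scale with UV-B in Col-0 (adjusted p = 3.84e-05). The labels do not say which uvr8 allele was used, so the position of the mutation within the gene was not set against these values.

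UV-B for 3 h raised single genes such as ELIP1 and CHS in Col-0 from low levels, and lowered others such as EXPA8. ELIP1, which encodes an early light-induced protein of the thylakoid membrane (AT3G22840, chromosome 3, 8084405 to 8085669), rose from 0.89 ± 0.14 to 1731.06 ± 36.06 TPM (SD, n = 3). CHS, the gene for chalcone synthase, which opens flavonoid synthesis (AT5G13930, chromosome 5, 4488476 to 4490264), rose from 31.25 ± 2.96 to 2263.33 ± 320.43 TPM. At the other end EXPA8, an expansin gene of cell wall loosening, fell from 16.7 ± 0.97 to 1.43 ± 0.35 TPM. With the limma test, 7994 of 19922 genes passed, 2451 of them higher and 5543 lower, and 1309 changed at least 2-fold, 788 upward and 521 downward.

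**Figure D1:**
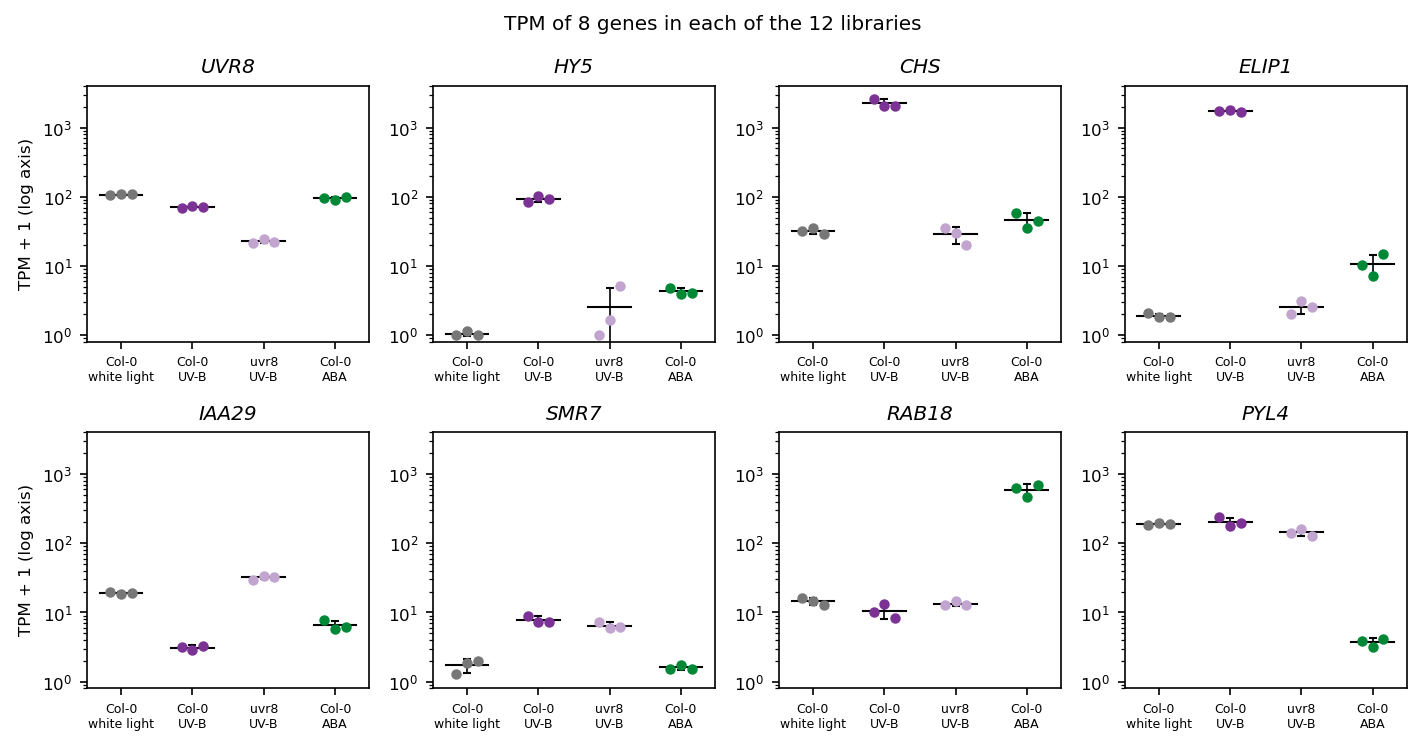
TPM + 1 of 8 genes on a log axis in the 4 groups, with a point for each of the 12 libraries, a line for the group mean and a bar for its SD. ELIP1 and CHS have means of 1731.06 and 2263.33 TPM under UV-B in Col-0 and of 1.57 and 27.58 TPM in uvr8 under UV-B.

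All 20 tested members of the UVR8 photomorphogenesis list rose with UV-B, both over all genes and adjusted over the list alone, and their median log2 change lay 4.24 above that of all genes (camera adjusted p = 7.06e-33, and adjusted p = 0.000612 with an estimated correlation). ELIP1 rose by 9.84 ± 0.22 log2 units on the log2(TPM + 1) scale (adjusted p = 1.92e-11). ELIP2, its close relative, was listed at 0 in 2 white-light libraries and at 0.63 TPM in the first replicate, and reached 2032.4, 2279.32 and 2127.85 TPM under UV-B. UGT84A1, a glucosyltransferase gene acting on hydroxycinnamic acids, rose from 0.39 ± 0.24 to 177.64 ± 20.61 TPM. HY5, the bZIP transcription factor of photomorphogenesis, was listed at 0, 0.16 and 0 TPM in white light and held 83.35, 101.31 and 92.59 TPM under UV-B. MPC2, a mitochondrial pyruvate carrier gene that starts 245 bp beyond ELIP2 on the same strand, held 351.09, 77.39 and 106.29 TPM, a spread that leaves its own rise uncertain because reads running past ELIP2 cannot be separated from it here.

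The flavonoid and phenylpropanoid list moved almost as one with UV-B. Of its 33 members 29 rose and 1 fell over all genes, or 30 and 2 adjusted over the list alone, with a median 3.43 above all genes (camera adjusted p = 2.61e-36, and adjusted p = 0.00748 with an estimated correlation). F3H, which encodes flavanone 3-hydroxylase, rose by 7.37 ± 0.15 log2 units from 5.65 to 1099.8 TPM (adjusted p = 1.29e-11). FLS1, the flavonol synthase gene, rose by 6.26 ± 0.14 to 742.24 TPM, and CHS by 6.13 ± 0.21 (adjusted p = 2.11e-11 and 6.34e-10). An antisense gene shares 1415 bp of exon with F3H, so its reads cannot be told from those of F3H without strand information. The circadian clock list also rose, with 11 of 13 members higher and none lower, also adjusted over the list alone (camera adjusted p = 2.55e-10, and adjusted p = 0.0235 with an estimated correlation). RVE8, a MYB-like clock activator, went from 0.8 ± 0.27 to 8.01 ± 1.41 TPM.

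Of 33 genes of auxin signalling and elongation growth 28 were lower with UV-B and 1 higher, or 28 and 2 adjusted over the list alone, with a median 0.9 log2 units below all genes (difference -0.9, camera adjusted p = 4.43e-09). That call was lost at adjusted p = 0.159 with an estimated correlation. EXPA8 fell by 2.87 ± 0.18 log2 units (adjusted p = 2.29e-07). Among the 5 lowest genes were also AT5G62280, from 58.01 to 6.88 TPM, the dormancy-associated DRMH1, from 128.74 to 18.1 TPM, and the acyl-lipid desaturase gene ADS1, from 19.16 to 1.98 TPM. AT1G09027, a small nucleolar RNA gene of 133 bp, held 102.74, 40.76 and 1.71 TPM in white light and was listed at 0 in all UV-B libraries of Col-0. In uvr8 under UV-B it held 0, 104.19 and 70.73 TPM, so the difference is uncertain at this length and spread.

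The ABA-related lists split under UV-B. Of 25 core signalling genes 5 rose and 6 fell, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.864), and after TMM-style scaling 5 rose and 3 fell. OST1, a kinase that activates ABA responses, rose from 10.6 ± 0.97 to 19.05 ± 1.88 TPM, while the related kinase gene SNRK2.2 fell from 123.03 ± 3.13 to 71.26 ± 4.49 TPM. Of 29 drought-response genes 9 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.0367). That call was lost at adjusted p = 0.58 with an estimated correlation and at 0.124 after scaling, where 11 rose and 4 fell. COR15B, a cold-regulated gene for a chloroplast protein, rose from 231.5 ± 17.24 to 614.28 ± 78.36 TPM. In the list of ABA synthesis, turnover and transport, 3 of 12 rose and 6 fell (camera adjusted p = 0.915), 3 and 3 after scaling. The 3 that rose were CYP707A2, whose product inactivates ABA, from 3.26 ± 0.49 to 21.03 ± 1.33 TPM, the zeaxanthin epoxidase gene ABA1, from 32.28 ± 2.6 to 133.47 ± 11.43 TPM, and CYP707A4, from 1.97 ± 0.41 to 6.22 ± 0.84 TPM.

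Smaller lists gave mixed counts with UV-B. Among early stress transcription factors 6 of 19 rose and 1 fell (camera adjusted p = 0.000491, and adjusted p = 0.36 with an estimated correlation), led by DREB2A, from 5.07 ± 0.41 to 44.89 ± 6.61 TPM. Of 16 antioxidant and detoxification genes 7 rose and 3 fell (camera adjusted p = 0.0136, and adjusted p = 0.355 with an estimated correlation), and the catalase gene CAT2 rose from 55.37 ± 3.03 to 530.08 ± 79.35 TPM. Glucosinolate synthesis had 7 of 9 lower and none higher (camera adjusted p = 0.0136, and adjusted p = 0.522 with an estimated correlation). Aquaporins had 8 of 17 lower (camera adjusted p = 0.0388, and adjusted p = 0.58 with an estimated correlation), or 7 lower and 2 higher after scaling at adjusted p = 0.0938. Heat shock genes had 3 of 15 higher (camera adjusted p = 0.0478, and adjusted p = 0.522 with an estimated correlation), 0.0938 after scaling. In the DNA damage list 5 of 13 rose and 1 fell (camera adjusted p = 0.0597), among them SMR7, a cell cycle inhibitor, from 0.72 ± 0.39 to 6.88 ± 0.92 TPM. The salicylate and defence list had 2 higher and 4 lower of 17, 3 and 1 after scaling (camera adjusted p = 0.94), with PR5, a pathogenesis-related gene, up from 6.86 ± 0.43 to 37.69 ± 4.47 TPM. Jasmonate genes had 2 higher and 7 lower of 17, 3 and 5 after scaling, and photosynthetic antenna and Rubisco genes 5 higher and 6 lower of 25, which turned to 8 and 2 after scaling (camera adjusted p = 0.915 and 0.55). No cell cycle or guard cell marker of 5 each passed, 2 of 5 wax genes fell, 1 of them after scaling, where 1 other wax and 1 guard cell gene rose, and of the 4 root markers tested 3 fell, or 1 after scaling. Adjusted over the list alone, the counts for these lists and for ABA synthesis were the same except for 8 glucosinolate genes, 9 aquaporins and 4 root markers lower, 2 heat shock genes higher, and 2 salicylate genes in each direction.

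The direction of the smaller UV-B changes depends on the scale. The median of all genes lay at -0.15 on the log2 scale, and after TMM-style scaling it lay near 0 and 3774 genes were higher and 3438 lower in place of 2451 and 5543, with 2448 and 3438 called under both and none called in opposite directions.

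The comparison of uvr8 with Col-0 under UV-B asked which of the levels reached under UV-B differ without the photoreceptor. With no uvr8 in white light, a difference cannot be told apart from one already present without UV-B. Most genes with a large UV-B change in Col-0 differed in the opposite direction in uvr8. ELIP1 stood at 1.57 ± 0.55 TPM in uvr8 under UV-B against 1731.06 ± 36.06 in Col-0, CHS at 27.58 ± 7.73 against 2263.33 ± 320.43, and F3H at 4.85 ± 0.52 against 1099.8 ± 52.53 (SD, n = 3). The auxin-response repressor gene IAA29 stood higher in uvr8, with 31.27 ± 2.15 against 2.11 ± 0.22 TPM, while the white-light Col-0 libraries held 18.54, 17.22 and 17.89 TPM. In all 8756 genes differed, 6538 higher and 2218 lower in uvr8, and 1504 by at least 2-fold, 805 higher and 699 lower.

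All 20 tested UVR8 photomorphogenesis genes were lower in uvr8, over all genes and adjusted over the list alone, with a median log2 difference of -4.39 from all genes (camera adjusted p = 3.34e-34, and adjusted p = 0.000528 with an estimated correlation). ELIP1 was lower by a log2 difference of -9.42 ± 0.22 (adjusted p = 2.7e-11), and UGT84A1 by -6.83 ± 0.18, at 0.57 ± 0.23 TPM. ELIP2 held 1.35 TPM in the first uvr8 replicate and was listed at 0 in the others. HY5 held 0, 0.64 and 4.08 TPM. Of the 33 flavonoid and phenylpropanoid genes 30 were lower and 2 higher, adjusted over the list alone as well (camera adjusted p = 3.31e-40, and adjusted p = 0.00535 with an estimated correlation). The clock list was lower in 9 of 13 members, also adjusted over the list alone (camera adjusted p = 4.3e-10, and adjusted p = 0.0252 with an estimated correlation). AT5G62210, which lies on chromosome 5 at 24986294 to 24987811, was lower by a log2 difference of -6.98 ± 0.14, with 1.49 against 309.81 TPM.

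Auxin and elongation genes were higher in uvr8 in 28 of 33 members and lower in 1, or 29 and 1 adjusted over the list alone (camera adjusted p = 9.54e-08, and adjusted p = 0.223 with an estimated correlation). IAA29 was higher by 3.38 ± 0.12 log2 units (adjusted p = 9.38e-10) and GH3.3, whose product conjugates auxin to amino acids, by 3.29 ± 0.19, at 82.48 ± 10.16 against 7.62 ± 1.8 TPM. Both also stood above white-light Col-0, where IAA29 held between 17.22 and 18.54 TPM and GH3.3 between 39.38 and 49.36. Their differences between the genotypes therefore exceed the UV-B change in Col-0. Salicylate and defence genes were higher in 14 of 17 and lower in 1, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.0175, and adjusted p = 0.752 with an estimated correlation). PR1, a marker of salicylate responses, stood at 68.52 ± 24.37 against 7.07 ± 2.86 TPM. The gene that stood furthest above Col-0 was AT1G75945, annotated as protein-coding on chromosome 1 at 28515245 to 28515916, with 62.97 ± 2.05 against 2.15 ± 0.51 TPM, a log2 difference of 4.36 ± 0.17 (adjusted p = 3.13e-09). AT3G02275, a non-coding RNA of 241 bp inside an antisense gene, held 13.39, 11.94 and 9.41 TPM in uvr8 and 0.6, 0 and 0 in Col-0 under UV-B, and is uncertain for its length.

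Among ABA-related genes CYP707A2 and ABA1 were lower in uvr8 by log2 differences of -2.35 ± 0.13 and -1.85 ± 0.12 (adjusted p = 7.01e-08 and 1.85e-07), and the ABA transporter gene ABCG40 was higher by 1.37 ± 0.27 (adjusted p = 0.0015). The list of synthesis, turnover and transport had 6 of 12 higher and 3 lower, or 8 and 3 adjusted over the list alone, and 4 and 3 after scaling (camera adjusted p = 0.917). Core signalling had 9 of 25 higher and 6 lower, which became 4 and 7 after scaling (camera adjusted p = 0.917). The drought list had 6 of 29 higher and 6 lower, 4 and 11 after scaling (camera adjusted p = 0.0564), and COR15A and COR15B, whose genes lie 8 bp apart, were lower by -1.37 ± 0.14 and -1.34 ± 0.1. Photosynthetic antenna and Rubisco genes were lower in 7 of 25 and higher in 1, or 13 and 0 after scaling (camera adjusted p = 0.000691, and adjusted p = 0.752 with an estimated correlation). The catalase gene CAT2 was lower by -3.07 ± 0.11, while the antioxidant list had 9 of 16 higher and 4 lower, 6 and 4 after scaling (camera adjusted p = 0.917). Adjusted over the list alone, 6 antenna genes were lower and 10 antioxidant genes higher, and the other counts for core signalling, drought, antenna and antioxidant genes were the same. The median of all genes lay at 0.2 on the log2 scale, and after scaling 3704 genes were higher and 3787 lower, of which 3703 and 2218 were also called without it.

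Of the 7994 genes changed by UV-B in Col-0, 6390 (79.9%) were called in the opposite direction in uvr8 under UV-B, 1844 that rose with UV-B and 4546 that fell. Of the 1309 UV-B changes of at least 2-fold, 1221 (93.3%) were called oppositely. For these 1309 genes uvr8 under UV-B differed from Col-0 in white light by a median of 6.52% of the UV-B change. That difference holds genotype as well as light, and 134 of the genes were called in it in the same direction as with UV-B. For the full lists, without the 2-fold limit, independent lists would share 273 and 1819 genes, beside the 1844 and 4546 counted. The larger direction depends on the scale: after TMM-style scaling 2959 that rose and 2472 that fell were called oppositely, 5431 in all (718 and 640 for independent lists). The comparisons share the UV-B libraries of Col-0. In 20 simulations of unchanged groups with that sharing the mean was 0 such genes, but unchanged groups give almost no calls, so this does not measure what the shared libraries add between changed lists. Across genes, which are not independent replicates, the log2 changes had a Pearson r of -0.869 (simulated -0.488) and a Spearman rho of -0.802. Their covariance was -0.369 against -0.0227 simulated, a difference of -0.346. The 3 shared libraries are too few to be split into parts of 2, so part of the excess may come from them. Without replicate 2 of every group the count was 3737, and without replicate 3 it was 4045.

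**Figure D2:**
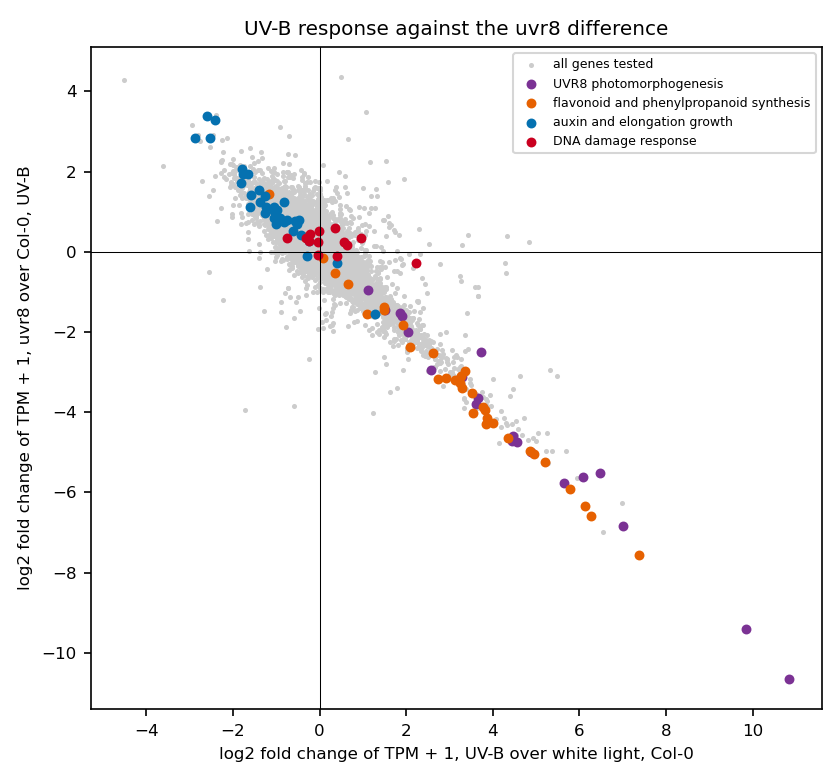
Log2 change of TPM + 1 with UV-B in Col-0 (x axis) against the log2 difference of uvr8 from Col-0 under UV-B (y axis), with grey points for all genes tested and coloured points for 4 gene lists. UVR8 photomorphogenesis and flavonoid genes run down to the right, all 20 of the first list above 0 on the x axis and below 0 on the y axis, and auxin and elongation genes lie mostly to the upper left.

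ABA for 3 h in white light raised single genes such as LEA7 and RAB18 and lowered others such as PYL4. The late embryogenesis abundant gene LEA7 (chromosome 1, 19619724 to 19621534) rose from 3.9 ± 3.91 to 509.97 ± 97.45 TPM (SD, n = 3). RAB18, a dehydrin gene widely used as an ABA marker (chromosome 5, 26518277 to 26519447), rose from 13.55 ± 1.58 to 593.19 ± 114.5 TPM. PYL4, which encodes an ABA receptor (AT2G38310, chromosome 2, 16049918 to 16051356), fell from 190.02 ± 7.93 to 2.75 ± 0.51 TPM. In all 10881 genes changed, 3030 higher and 7851 lower, of which 2245 changed at least 2-fold, 1173 upward and 1072 downward.

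Of the 29 drought-response genes 28 rose and none fell, over all genes and adjusted over the list alone, with a median 4.21 log2 units above all genes (camera adjusted p = 1.68e-32, and adjusted p = 0.0146 with an estimated correlation). LEA4-5 rose by 6.36 ± 0.34 log2 units (adjusted p = 3.43e-08), TSPO, a membrane protein gene, by 5.66 ± 0.32 (adjusted p = 5.18e-08) and RAB18 by 5.34 ± 0.18 (adjusted p = 1.08e-09). Outside the lists AT3G02480 and the lipid transfer protein gene LTP4 were among the 5 highest, at 520.49 ± 72.51 and 374.5 ± 42.66 TPM from 4.99 ± 3.54 and 3.62 ± 0.68. Among the 5 lowest were AT1G27020, from 68.68 ± 9.43 to 1.8 ± 0.11 TPM, and the small heat shock protein gene HSP15.4, from 36.55 ± 4.19 to 1.16 ± 0.14 TPM.

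Core signalling genes changed in both directions with ABA. Of 25 members 15 rose and 7 fell, also adjusted over the list alone and after scaling (camera adjusted p = 2.16e-05, and adjusted p = 0.0626 with an estimated correlation). The phosphatase genes HAI1 and HAI2, negative regulators of the pathway, rose by 6.44 ± 0.2 and 5.41 ± 0.26 log2 units (adjusted p = 6.47e-10 and 1.52e-08). The receptor gene PYL4 fell by 5.68 ± 0.13 (adjusted p = 1.56e-10), and PYL6 went from 16.58, 17.83 and 22.22 TPM to 0.04, 0.04 and a listed 0. In the list of ABA synthesis, turnover and transport 9 of 12 rose and 2 fell, 10 and 2 adjusted over the list alone, and 10 rose with none lower after scaling (camera adjusted p = 6.48e-08, and adjusted p = 0.0626 with an estimated correlation). CYP707A1, CYP707A3 and CYP707A4, whose products inactivate ABA, rose by 3.53 ± 0.11, 2.42 ± 0.12 and 3.53 ± 0.15 log2 units.

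Members of the photomorphogenesis, flavonoid and auxin lists also changed with ABA, though none of these 3 lists kept its call with an estimated correlation. Of the 20 UVR8 photomorphogenesis genes 11 rose and 3 fell, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.000191, and adjusted p = 0.0992 with an estimated correlation). ELIP1 rose from 0.89 ± 0.14 to 9.71 ± 3.81 TPM, and SIG5, a plastid sigma factor gene, from 1.85 ± 0.11 to 11.79 ± 0.84 TPM. Flavonoid and phenylpropanoid genes rose in 17 of 33 cases and fell in 7, or 19 and 7 adjusted over the list alone, and 21 and 4 after scaling (camera adjusted p = 2.16e-05, and adjusted p = 0.258 with an estimated correlation). The anthocyanin regulators PAP1 and TT8 rose from 4.45 ± 0.91 to 20.77 ± 2.51 and from 1.83 ± 0.03 to 11 ± 1.5 TPM, as did LDOX, an anthocyanin synthesis gene with a near-identical copy, from 3.75 ± 0.79 to 19.92 ± 5.84 TPM. Auxin and elongation genes fell in 24 of 33 cases and rose in 4, 22 and 6 after scaling (camera adjusted p = 0.00144, and adjusted p = 0.311 with an estimated correlation), with EXPA8 at 0.88 ± 0.34 TPM.

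All 5 cuticular wax genes tested rose with ABA (camera adjusted p = 7.52e-07, and adjusted p = 0.0626 with an estimated correlation), led by CER1, an alkane synthesis gene, from 33.61 ± 1.62 to 335.09 ± 69.35 TPM. Aquaporins rose in 11 of 17 cases and fell in 4, or 12 and 0 after scaling (camera adjusted p = 6.17e-05, and adjusted p = 0.258 with an estimated correlation), and PIP1;1 rose from 159.69 ± 6.89 to 651.07 ± 19.23 TPM. Of the jasmonate genes 10 of 17 rose and 2 fell (camera adjusted p = 0.000474, and adjusted p = 0.258 with an estimated correlation), including the storage protein gene VSP2, from 25.12 ± 9.96 to 452.2 ± 154.53 TPM. Early stress transcription factors rose in 11 of 19 cases and fell in 6 (camera adjusted p = 0.00314, and adjusted p = 0.311 with an estimated correlation). Antioxidant genes rose in 6 of 16 cases and fell in 4, or 11 and 3 after scaling (camera adjusted p = 0.0224), and clock genes rose in 6 of 13 (camera adjusted p = 0.011), both at adjusted p = 0.258 with an estimated correlation. Antenna and Rubisco genes fell in 17 of 25 cases, but in 3 after scaling (camera adjusted p = 0.0228, adjusted p = 0.633 with an estimated correlation, 0.0886 after scaling), and the Rubisco small subunit gene RBCS1B fell by 2.3 ± 0.11 log2 units (adjusted p = 1.41e-08). DNA damage genes fell in 7 of 13 cases (5 after scaling, where the list passed at adjusted p = 0.0387), glucosinolate genes fell in 7 of 9 and rose in 2, and salicylate genes fell in 7 of 17 and rose in 1, or 5 and 2 after scaling (camera adjusted p = 0.0777, 0.239 and 0.816). Of 5 guard cell markers 3 fell, among them MYB60, from 14.62 ± 0.97 to 2.73 ± 0.7 TPM, and 1 rose. Of 4 root markers 3 fell and 1 rose, and of 5 cell cycle genes CDKB2;1 fell at adjusted p = 0.0491, a call lost adjusted over the list alone and after scaling (adjusted p = 0.29). Heat shock genes rose in 3 of 15 cases and fell in 2 (camera adjusted p = 0.426). Adjusted over the list alone, 18 antenna genes fell, and 7 antioxidant, 2 heat shock and 2 guard cell genes rose, with the same counts otherwise for these lists and for auxin.

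The ABA libraries also held larger shares of ribosomal and plastid-encoded RNA. Ribosomal RNA took 3.83% ± 1.15 of TPM against 2.44% ± 0.4 in white light, and plastid-encoded genes 1.33% ± 0.302 against 0.451% ± 0.112. The ribosomal ranges nearly touched, with 2.867% in ABA replicate 3 and 2.861% in white-light replicate 1. The median of all genes lay at -0.24 on the log2 scale, and after scaling 4754 genes were higher and 4307 lower, of which 3025 and 4307 were also called without it.

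Between uvr8 under UV-B and Col-0 in white light, where light and genotype differ together, fewer genes passed than in any other comparison. ELIP1 (1.57 ± 0.55 against 0.89 ± 0.14 TPM, adjusted p = 0.325) and CHS (27.58 ± 7.73 against 31.25 ± 2.96 TPM, adjusted p = 0.667) did not pass. SMR7 stood higher in uvr8 at 5.46 ± 0.72 TPM, a log2 difference of 1.93 ± 0.18 (adjusted p = 0.000119), and AT1G75945 differed by 4.85 ± 0.17 (adjusted p = 2.55e-08). PR1 was higher by 2.21 ± 0.34 (adjusted p = 0.00359) and HSP23.6, a mitochondrial small heat shock protein gene, by 1.44 ± 0.16 (adjusted p = 0.000408). In all 1018 genes differed, 763 higher and 255 lower, or 662 and 417 after scaling, with 604 and 238 called under both.

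Of 17 salicylate and defence genes 8 were higher than in white-light Col-0 and none lower, or 12 and 0 adjusted over the list alone (camera adjusted p = 4.03e-10, and adjusted p = 0.211 with an estimated correlation). Antioxidant genes were higher in 10 of 16 and lower in 1, or 11 and 1 adjusted over the list alone, and 8 and 1 after scaling (camera adjusted p = 4.57e-07, and adjusted p = 0.118 with an estimated correlation), and the glutathione transferase gene GSTU4 was higher by 1.33 ± 0.17. Early stress transcription factors were higher in 6 of 19, or 12 adjusted over the list alone (camera adjusted p = 4.57e-07, and adjusted p = 0.211 with an estimated correlation). DNA damage genes were higher in 6 of 13, or 6 with 1 lower adjusted over the list alone (camera adjusted p = 0.000166, and adjusted p = 0.241 with an estimated correlation). Glucosinolate genes were lower in 3 of 9, or 8 adjusted over the list alone and 6 after scaling (camera adjusted p = 6.93e-07, and adjusted p = 0.211 with an estimated correlation). Antenna genes were lower in 3 of 25, or 9 adjusted over the list alone, and in 1 after scaling (camera adjusted p = 4.57e-07, and adjusted p = 0.404 with an estimated correlation). Aquaporins were lower in 3 of 17, or 5 adjusted over the list alone, and in none after scaling (camera adjusted p = 4.41e-06, and adjusted p = 0.241 with an estimated correlation). Wax genes were lower in 2 of 5, or 3 adjusted over the list alone (camera adjusted p = 0.00248, and adjusted p = 0.241 with an estimated correlation). Of 33 flavonoid and phenylpropanoid genes 1 was lower, also adjusted over the list alone, or 2 after scaling (camera adjusted p = 0.000939, and adjusted p = 0.404 with an estimated correlation). Of the UVR8 photomorphogenesis genes 2 of 20 were higher (camera adjusted p = 0.73), also adjusted over the list alone, 1 of them SIG5 by 0.46 ± 0.09. The count of 1018 genes moved with single libraries: it was 426, 614 and 632 without white-light replicate 1, 2 or 3, and 584 and 549 without uvr8 replicate 1 or 2.

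The last question was how far the responses to UV-B and to ABA overlap in Col-0. UV-B gave the higher level of UVR8 photomorphogenesis genes and ABA that of drought genes, and the direct test between the treatments called 11147 genes, 6390 higher under UV-B and 4757 higher under ABA. Counts adjusted over the list alone equal those over all genes here except where given. All 20 photomorphogenesis genes were higher under UV-B (camera adjusted p = 3.31e-14, and adjusted p = 0.0122 with an estimated correlation), while 26 of 29 drought genes were higher under ABA and 1 under UV-B, or 26 and 0 after scaling (camera adjusted p = 4.8e-18, and adjusted p = 0.0435 with an estimated correlation). RAB18 differed by -5.82 log2 units and PYL4 by 5.76 (adjusted p = 1.74e-10 and 2.58e-11). CYP707A2 and ABA1, which rose with each treatment, did not pass the direct test, at log2 differences of -0.02 ± 0.13 and 0.21 ± 0.12 (adjusted p = 0.889 and 0.139). Flavonoid genes were higher under UV-B in 28 of 33 and under ABA in 2 (camera adjusted p = 1.88e-13, and adjusted p = 0.0937 with an estimated correlation). The auxin and elongation list, in which 28 members fell with UV-B and 24 with ABA, had 10 of 33 higher under each, or 11 adjusted over the list alone (camera adjusted p = 0.463). Aquaporins were higher under ABA in 14 of 17 and under UV-B in 1 (camera adjusted p = 6.22e-06, and adjusted p = 0.191 with an estimated correlation), and PIP1;3 had fallen by 1.05 ± 0.12 log2 units with UV-B and risen by 1.06 ± 0.12 with ABA. Of the other lists that passed, core signalling, ABA synthesis, wax and jasmonate genes leaned to ABA (camera adjusted p = 0.00128, 4.43e-05, 4.43e-05 and 0.00314) and lost the call with an estimated correlation (adjusted p = 0.132, 0.132, 0.101 and 0.337). Clock, DNA damage and antenna genes leaned to UV-B (camera adjusted p = 0.00181, 0.0134 and 0.0406) and lost it too (adjusted p = 0.191, 0.441 and 0.887), the last also after scaling (0.0727).

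**Figure D3:**
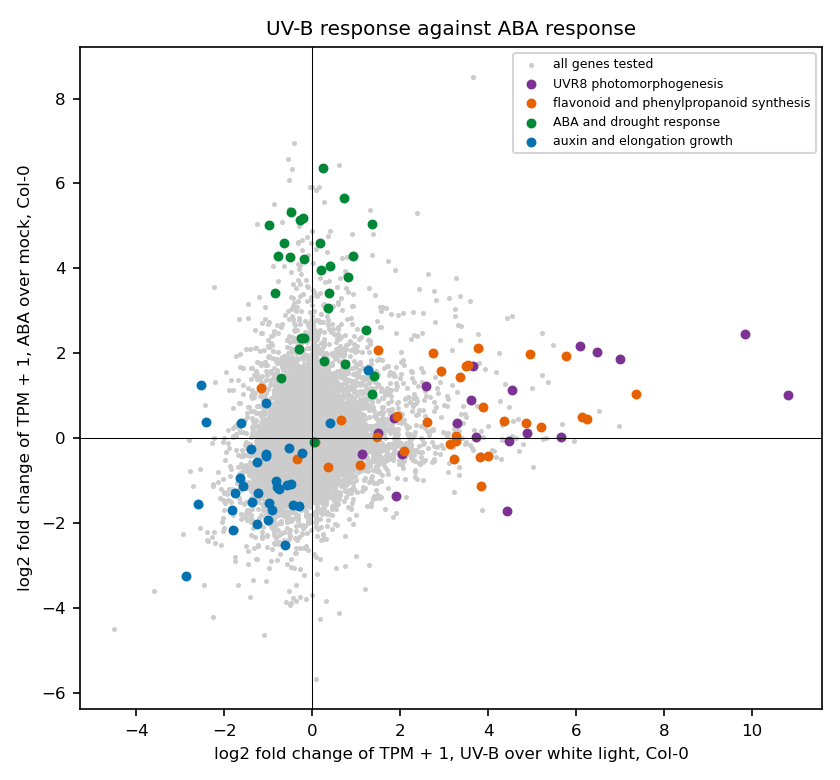
Log2 change of TPM + 1 with UV-B (x axis) against that with ABA (y axis) in Col-0, with grey points for all genes tested and coloured points for 4 gene lists. Drought genes extend upward with ABA (RAB18 at 5.34) and photomorphogenesis genes to the right with UV-B (ELIP1 at 9.84), while most auxin and elongation genes lie to the lower left.

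In the same direction 3177 genes changed with both treatments, 699 higher and 2478 lower, where independent lists of these sizes would share 373 and 2184. Another 1830 changed in opposite directions, 889 higher with UV-B and lower with ABA (966 for independent lists) and 941 the reverse (843). After TMM-style scaling the same-direction counts were 1246 higher and 1039 lower (902 and 744 for independent lists), and the opposite ones 904 and 1016 (817 and 821), so the larger direction and the shortfall at 889 depend on the scale. The treatments share the white-light libraries. A mean of 0 shared calls in 20 simulations of unchanged groups, which give almost no calls, does not measure what that sharing adds. Across genes the log2 changes had a Pearson r of 0.193 (simulated 0.497 for unchanged groups) and a Spearman rho of 0.103, with a covariance of 0.0958 against 0.0232 simulated, a difference of 0.0725. The 3 shared libraries are too few to be split into parts of 2, so part of this may come from them. The same-direction count was 1641 without replicate 2 of every group and 1774 without replicate 3. The opposite counts of 889 and 941 became 420 and 542 without replicate 2, and 420 and 463 without replicate 3.

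The ABA and uvr8 comparisons share no library. They do share each gene's spread, estimated from all 12 libraries, so genes of low spread are more easily called in both. Part of any excess over independent lists may come from this. Genes that rose with ABA and were lower in uvr8 numbered 577 (337 for independent lists, odds ratio 2.19, Fisher's exact test across genes p = 5.94e-45), and those that rose with ABA and were higher in uvr8 numbered 1275 (994, odds ratio 1.61, p = 4.57e-31). By the same exact test, genes that fell with ABA were higher in uvr8 in 2400 cases (2577, odds ratio 0.844, p = 5.01e-08) and lower in 911 (874, odds ratio 1.08, p = 0.0925). These p-values describe genes that are not independent of one another. The log2 changes had a Pearson r of -0.071 and a Spearman rho of 0.047 across genes. After TMM-style scaling genes that rose with ABA were lower in uvr8 in 1089 cases and higher in 1340 (905 and 885 for independent lists), and those that fell were higher in 836 and lower in 1167 (802 and 820), so the shortfall at 2400 is not kept. The 2977 genes called in opposite directions became 1925 after scaling, and 1966, 1520 and 1808 without replicate 1, 2 or 3 of every group.

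**Figure D4:**
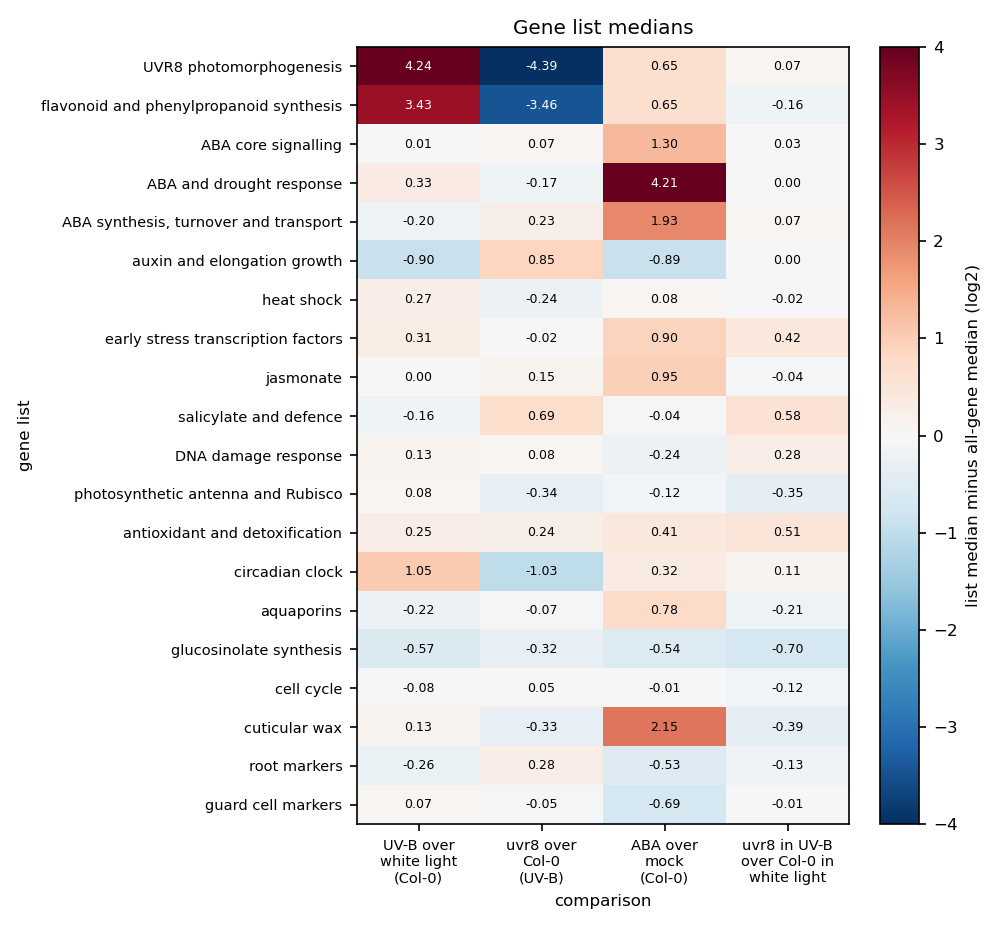
Median log2 change of each gene list minus that of all genes (printed in each cell), with lists on the y axis, 4 comparisons on the x axis and a colour scale limited to 4 log2 units in either direction. The UVR8 photomorphogenesis list stands at 4.24 with UV-B and -4.39 in uvr8, and the ABA and drought response list at 4.21 with ABA.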

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

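The setting that leaves out ribosomal, organelle and short genes, and the scaling of the gene lists, were chosen after the results were seen. Of the summary results under other settings, 88 values stayed within 1.5 times the value given in the report and 26 did not. For named genes 1350 values kept their direction and side of the threshold, 22 lost the call, 2 gained one and 1 reversed. The 22 belong to AT1G09027 and CDKB2;1. UVR8 with ABA turned from -0.17 to 0.078 on the log2 scale after TMM-style scaling (not called in either), and passed at adjusted p = 0.042 with no filter and 0.0495 without ABA replicate 3.

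A minimum log2 change of 1 left 1309 genes with UV-B, 1504 in uvr8, 2245 with ABA, 190 between uvr8 under UV-B and Col-0 in white light, and 3154 between UV-B and ABA. It left 959 opposite calls between UV-B and uvr8, 330 calls in the same direction with UV-B and ABA, and 293 opposite calls between ABA and uvr8. Fewer genes pass 2 criteria by construction. TMM-style scaling gave 1925 of the last kind, and the cause was not tested beyond the shift of the median gene.

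Leaving out 1 library gave 6337 to 7680 genes with UV-B, 7160 to 8798 in uvr8, 9265 to 10344 with ABA, 426 to 765 between uvr8 under UV-B and Col-0 in white light, and 9985 to 10732 between UV-B and ABA. Without 1 replicate number in every group the overlaps were 3737 to 4858 (UV-B and uvr8), 1641 to 2223 (UV-B and ABA) and 1520 to 1966 (ABA and uvr8). Fewer libraries leave fewer degrees of freedom. Depth cannot be weighed because TPM keeps none.

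With an estimated correlation the lists that passed went from 10 to 3 with UV-B, from 6 to 3 in uvr8, from 13 to 1 with ABA, from 9 to 0 between uvr8 under UV-B and white light, and from 11 to 2 between UV-B and ABA. An estimated correlation widens the spread of a list whose genes vary together. Fry asks whether a list moved at all, not whether it moved more than other genes. By fry the auxin list passed with UV-B and in uvr8 (adjusted p = 1.21e-06 and 1.17e-06). The photomorphogenesis list passed with ABA (fry adjusted p = 1.88e-05) and the salicylate list in uvr8 against white light (0.00292). The drought list with UV-B did not pass (fry adjusted p = 0.0593). Nor did the flavonoid and antenna lists in uvr8 against white light (0.249 and 0.159).

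Whether the replicate numbers pair the libraries stays open. Deviations of the 18 pairs with the same number correlated between -0.132 and 0.256, 7 of them over 0.1, and 6 of 12 libraries correlated best with their own number. With the replicate number as a block 7656, 8481, 10611, 870 and 10981 genes passed in the order of comparisons above, and 10, 6, 13, 9 and 11 lists.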

Other observations

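The tests of the TPM scale, of poly(A) selection and of the rDNA repeat were chosen only after the results they bear on were seen, and the genes named in this part were chosen after their values were seen.

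A small set of genes stood higher under UV-B in both genotypes than in Col-0 in white light. At least 2-fold higher in both were 44 genes, where independent lists of these sizes would share 7, and 3 were lower in both. Both comparisons use the same white-light libraries, which adds to such an overlap, and uvr8 in white light was not analysed here. UGT73C6, a flavonol glycosyltransferase gene, rose by 2.32 ± 0.20 log2 units in Col-0 (adjusted p = 3.11e-06) and stood 2.26 above white light in uvr8. UPOX, a nuclear gene for a mitochondrial protein, is induced by oxidative stress. Its transcript stood 1.84 and 2.24 above white light in Col-0 and uvr8, and that of OXI1, a kinase gene of oxidative signalling, 2.15 and 1.74. With ABA UGT73C6 and OXI1 did not pass (adjusted p = 0.788 and 0.171), while UPOX fell by 0.46 (adjusted p = 0.0265).

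A few genes stood apart in uvr8 from all other groups. MRD1 (chromosome 1, 19963047 to 19964712) was listed at 0 in all 3 uvr8 libraries, and held 18.34, 21.94 and 21.83 TPM in white light, 11.09, 12.47 and 17.01 under UV-B in Col-0, and 12.51, 21.48 and 15.35 with ABA. It shares 1122 bp of exon with antisense genes, so these values are uncertain. AT1G75945 held 62.97 TPM in uvr8 and between 0.8 and 2.15 as the mean of the other groups. Other genes differed by degree only. FSD1, an iron superoxide dismutase gene, differed from white-light Col-0 by -2.39 log2 units in uvr8, but also by -0.89 with UV-B and -1.56 with ABA in Col-0. UGT74E2, a glucosyltransferase gene acting on indole-butyric acid, stood 2.86 above white light in uvr8, and 1.3 and 2.03 with UV-B and ABA in Col-0.

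More genes fell than rose with UV-B (69.3% of calls) and with ABA (72.2%). Ribosomal RNA, organelle genes and short genes in the TPM total are argued against as the source, since 70.3% and 69.8% of calls still fell without them. A shift of the whole TPM scale stays open: after TMM-style scaling 47.7% and 47.5% fell, but that scaling puts the median gene near 0 and so nearly fixes the share, for which reason a first reading in favour was withdrawn after the values were seen. Genes at least 2-fold higher gained 7.49% of all TPM with UV-B and 11.5% with ABA. Those at least 2-fold lower lost 1.35% and 4.12%, and the median gene lost 10% and 15.2%. Genes that rose by less than 2-fold are not in these shares, so the shares do not show how much of the median gene's loss the scale explains. A loss of RNA from many genes, the biological alternative, cannot be told apart from a shift of the scale without an external standard.

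The genes that differ between uvr8 under UV-B and Col-0 in white light could come from a UV-B response without UVR8 or from the genotype. A region of another background around UVR8 is argued against only as the source of most of these genes. Of 596 genes that differ the same way from both Col-0 groups, 4.36% lie within 2 Mb of UVR8, against 4.03% of all genes tested. A few linked genes, or another background elsewhere in the genome, would not show in this share. The set of 596, with 520 higher and 76 lower genes, shrank to 149 and 19 without replicate 1 of every group. It shrank to 105 and 13 without replicate 2 and to 65 and 11 without replicate 3, and the share was not computed for these. In genes picked without 1 white-light library, 67.9% kept their sign with UV-B in Col-0 on average (76.3, 63.8 and 63.4%), and in genes picked without 1 uvr8 library 70.8% kept their sign against Col-0 under UV-B (70.4, 73.4 and 68.8%). Both means lie between the bounds set in advance, 55 and 75%. The 2 scores are linked, because the difference that picks the genes is the sum of the 2 differences scored. A gene then tends to keep its sign in at least 1 of them, so shares of this size do not decide between the explanations. With no uvr8 in white light the 2 explanations cannot be told apart gene by gene.

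At least 8-fold higher under UV-B in both Col-0 and uvr8 were 6 genes, and 5 of them (83.3%) lie within 5 kb upstream of an 18S ribosomal RNA gene or align to that stretch. The share among all genes tested, 0.0251%, is made up of these same 5 genes. They are AT2G01008, which rose by 4.32 log2 units in Col-0, MIR5642b, AT3G06325, AT3G41762 and AT2G16586 (98.8% identity over 608 bp), and the other is the spliceosomal RNA gene U2.10, 195 bp long. Their sequences are near-identical and their loci partly overlap, so the 5 may be 1 signal, and a candidate explanation is RNA from the spacer of the rDNA repeat under UV-B. More ribosomal RNA carried into the UV-B libraries stays open: the 18S gene AT3G41768 rose by 1.13 log2 units in Col-0, 0.26 of the median rise of 4.29, and in uvr8 0.23 of the median rise there, while the 5.8S gene AT2G01020 changed by -0.73 and -1.65 and all ribosomal RNA took 1.13% of TPM in uvr8 against 2.44% in white light. With ABA none of the 6 passed (adjusted p between 0.201 and 0.769), and no other biological explanation was tested.

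Weaker poly(A) selection in the ABA libraries was tested by the rise of mitochondrial over plastid ribosomal RNA, a ratio of 0.56 that ranged from 0.4 to 0.68 with 1 library of each group left out. Plastid, mitochondrial and cytosolic ribosomal RNA rose with ABA by 0.553, 0.307 and 0.473 on the log2 scale. With these rises the ratio of 0.56 met the criterion first set for weaker selection. The criterion of a ratio that holds without each library was added after that value was seen. The lowest ratio, 0.4, falls below the first bound, so the question is left open.

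Splits of each comparison's 6 libraries into 3 and 3 number 10, too few for a share under 0.05, since the real split is 1 of the 10. The real splits gave 7994, 8756, 10881, 1018 and 11147 genes in the order UV-B, uvr8, ABA, uvr8 against white light, and UV-B against ABA. The highest of the other splits gave 3, 2, 1, 2 and 1. Each of those splits mixes libraries of the compared groups, so a real group difference adds to the spread and leaves few calls. Their low counts are therefore no measure of what chance alone gives, and no conclusion is drawn from the contrast.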
